A study of Gallus gallus with 3 samples.

How the data were processed

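The study measured RNA from chick endoderm on 3 Affymetrix Chicken Genome Arrays, 1 each for early endoderm, foregut endoderm and mid/hindgut endoderm. Per the labels, tissue was gathered every 4 hours over 1 day and pooled, and 5 µg of total RNA was labelled for each array. Early endoderm was taken from the mesenchyme with needles. The later tissues were taken with mesenchyme, which was then removed after 30 minutes in 0.03% collagenase. The deposited values are signal intensities on a linear scale that the authors computed with MAS5, whose version and settings are not given in the sources used here. Detection calls were not used here, and an aligner or genome build does not apply to these values.

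The arrays' 2% trimmed means were 192 in early endoderm, 155 in foregut and 159.8 in mid/hindgut. They differed by more than 10%, so each array was scaled to their mean, by factors of 0.881, 1.09 and 1.06. The median log2 difference over genes was then 0.06 for foregut against early, 0.02 for mid/hindgut against early and 0.02 for foregut against mid/hindgut. Signals below the 40th percentile of chicken probe sets over the 3 arrays, 22.1 units, were set to that floor. For comparison, 1.31% of viral probe sets in early endoderm, 2.76% in foregut and 2.18% in mid/hindgut lay above it. Signal of the 3' end relative to the 5' end of actin was 1.55, 1.69 and 2.19 in the same order, and that of GAPDH 0.982, 0.972 and 1.01. The 27 hybridisation control probe sets, relative to early endoderm, stood at 0.724 in foregut and 1.07 in mid/hindgut. Pearson correlations across 9139 genes, which are not between replicates, were 0.914 for foregut and early, 0.928 for mid/hindgut and early and 0.934 for foregut and mid/hindgut.

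Of 38535 probe sets, 37693 were for chicken, 689 for viruses, 96 were controls and 57 reporters. The platform annotation gave 1 gene for 27178, several genes for 177, which were left out, and did not list 11180. Gene names were updated through gene identifiers to a current chicken gene table, in which 26863 probe sets were found; the others kept their older name. For each of 13050 genes the probe set with the highest mean floored log2 signal was used, and 7336 genes had more than 1. PDX1 had no named probe set. The 10527 chicken probe sets not assigned to 1 gene, which include those with several genes, were not used for named results.

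With 1 array per group no test was possible. Each comparison gives the log2 difference of floored signals and counts genes at least 2-fold and 4-fold apart, among genes above the floor on either array. Technical spread was the standard deviation of the difference in log2 ratio between 2 probe sets of 1 gene, divided by the square root of 2. It was taken over genes with 2 probe sets above the floor on all arrays, so noise near the floor was not estimated. From this spread 100 simulated draws gave the counts that it alone would produce. A total of 35 gene lists, holding 967 symbols of which 797 memberships were on the array, were written before the data were examined, as were the comparisons, the floor, the scaling rule and 10 alternatives. Each list's median was placed among 10000 random lists of its size matched in 20 bins of mean level.

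Genes named are the 10 highest and 10 lowest per comparison, up to 4 list members at least 2-fold apart per list and comparison, 12 genes fixed beforehand and every HOX gene on the array. Any other gene named, such as a single list member going against its list, a gene highest in 1 tissue, or a gene with opposite differences in the later tissues, was chosen after its values were seen. The lists are of 3 kinds. The pathway lists are endoderm transcription factors, gastrulation and primitive streak, foregut patterning, mid/hindgut patterning, 3 HOX paralog groups, differentiation of liver, pancreas and intestine, and signalling by Hedgehog, retinoic acid, Wnt, BMP with Nodal and TGF-beta, FGF and Notch. They continue with epithelial junctions, basement membrane, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, and cathepsins and lysosome. The technical lists are immediate early genes, heat shock and ribosomal proteins. The cell type lists are cardiac mesoderm, paraxial mesoderm, lateral and gut mesenchyme, notochord, blood, endothelium, neural ectoderm, neural crest, epiblast, germ cells, and yolk sac or hypoblast endoderm. After a first look at list values, the matching of old to new gene symbols was corrected on gene names alone, and 6 synonyms were left unmatched.

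The alternatives were quantile, median and ribosomal protein scaling, a floor at the 20th or 60th percentile, no floor, genes above the floor on all arrays, the median over a gene's probe sets, leaving out probe sets shared between transcripts, and 3-fold in place of 2-fold. Another 4 were chosen after seeing the data: scaling on hybridisation controls, deposited values without scaling, a floor at the 95th percentile of viral probe sets, and leaving out marker genes of other cell types. The steps were tested on simulated data with 50 genes at each of 4 set differences. These genes were drawn from those with a mean signal more than 2-fold above the floor. The unchanged genes included genes at the floor, and noise at the floor was not estimated. Set log2 differences of 1.5 and −1.5 were recovered at 2-fold in 92% and 86% of genes, and 3 and −3 in 100% and 96%, while 1.49% of unchanged genes passed. Apart from the simulation, 200 random lists of 20 genes were drawn from the real foregut against early differences, and 6% fell outside the central 95%. Such lists come from the same genes as the random lists they were placed among. The result therefore checks the procedure only and says nothing about lists of genes that change together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.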

Results

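RNA levels were measured in endoderm, the germ layer that lines the gut, dissected from chick embryos at 3 positions in stage and place. The early sample held the whole definitive endoderm of 500 embryos at Hamburger-Hamilton stages 4 to 5, when the primitive streak is fully extended and gastrulation is under way. The foregut sample came from stages 10 to 11 and lay in front of the anterior intestinal portal, the opening of the closing foregut. The mid/hindgut sample came from stages 8 to 10 and lay behind the prospective small intestine. Each sample was 1 pool collected over 1 day and was hybridised to 1 Affymetrix Chicken Genome Array, so each group has n = 1 and no difference has a replicate check or a p-value.

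The deposited signals had a median of 36.6 in early endoderm, 30.6 in foregut and 32.7 in mid/hindgut. After scaling, 58.9% of chicken probe sets in early endoderm, 60.2% in foregut and 60.8% in mid/hindgut lay above a floor of 22.1 signal units. Of 13050 named genes, 11159 lay above the floor on at least 1 array. The only repeat measurement within an array is a second probe set for the same gene, and over 4128 genes it gave a technical standard deviation of the log2 ratio of 0.43 for foregut against early, 0.31 for mid/hindgut against early and 0.36 for foregut against mid/hindgut. This spread covers probe noise, not variation between pools or embryos. All signals below are scaled signals, and a fold against an array at the floor is a lower bound, written as "at least". Folds against signals just above the floor are not so marked, but they are inexact, since noise there was not estimated. Examples are GUCA2B at 23.4, SOX18 at 22.4 and CA2 at 23.5 in early endoderm, and PKDCCA at 24.7 in mid/hindgut.

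The first comparison set foregut endoderm against early endoderm and asks what separates the front of the gut tube from the germ layer it arises from. Of 18 measured genes of foregut and pharynx patterning 8 were higher in foregut, led by NKX2-5, a factor of the heart field and pharyngeal endoderm, at a signal of 1630.1 against a floor value in early endoderm, at least 73.6-fold. Most measured genes of the gastrulation and posterior patterning lists were lower, led by CER1, a secreted inhibitor of Nodal and BMP, at least 119-fold, and by CDX4, a posterior homeobox gene, at least 83.3-fold. Most genes of the blood vessel endothelium list were higher, with CDH5, the adhesion molecule of endothelial junctions, at 2535 in foregut and below the floor in early endoderm, at least 115-fold.

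Of the 23 measured genes of the gastrulation and primitive streak list, 14 were at least 2-fold lower in foregut and 1, HESX1, was 2.01-fold higher, or 0.70 in log2 without scaling. The list had a median log2 difference of −2.40, below all of 10000 random lists matched on mean level. Over the genes above the floor on all arrays, which leaves out those at the floor in foregut, the median was −0.39. The streak and tail bud factor TBXT had a signal of 3598 in early endoderm and 98.2 in foregut, 36.6-fold lower. WNT8A was at least 30.6-fold lower and the Nodal-related ligand GDF3 at least 19.6-fold lower. The mid/hindgut patterning list had 10 of 12 measured genes lower, none higher, and a median of −1.87, also below all random lists. CDX2, which sets intestinal identity, was at least 21.7-fold lower, with 1 of 2 other measured probe sets for it going the other way and a log2 difference of −2.59 over the median of its probe sets, and CDX1 was 7.40-fold lower. WNT3A was at least 8.79-fold lower.

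The foregut patterning list had 8 of 18 measured genes higher and 1, SALL1, 2.42-fold lower, with a median of 0.69 above 99.95% of random lists, and 0.35 over the genes above the floor on all arrays. NKX2-6 was 23.5-fold higher, the LIM homeobox gene ISL1 14.7-fold, and PAX9, a gene of the pharyngeal pouches, 7.79-fold. SOX2, a marker of anterior gut endoderm, was below the floor in early endoderm and at 72.2 in foregut, at least 3.26-fold higher. SALL1 was within 2-fold at −0.81 in log2 with scaling on hybridisation controls, and SOX2 at 0.26 with a floor at the 60th percentile. NKX2-1, a marker of the lung and thyroid fields, had signals of 114 and 144, less than 2-fold apart. HHEX had a signal of 1600.3 in early endoderm and 1603 in foregut, and SHH was below the floor in early endoderm and at 37.3 in foregut. Among the HOX genes, few were above the floor on either of these arrays. Of paralog groups 1 to 4, 5 genes were measured and HOXB3 was 4.36-fold lower, or −1.12 in log2 over the median of its probe sets. Of groups 5 to 8, 2 genes were measured and HOXB5 was at least 2.05-fold lower. It was at −0.91 in log2 with scaling on hybridisation controls and at 0 with a floor at the 60th percentile. Of groups 9 to 13, 3 genes were measured and none differed by 2-fold.

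The general endoderm transcription factor list went both ways, with 2 of 12 measured genes higher and 4 lower and a median of −0.27 that became 0.17 when arrays were scaled on hybridisation controls. SOX17, an early endoderm factor, was 11.1-fold lower at 879 against 9773, and GATA6 was 8.17-fold lower. The 2 higher members, SOX18 at 55.7-fold and SOX7 at 7.02-fold, are also known from endothelium. Over the median of its probe sets SOX7 had a log2 difference of 1.405. FOXA2, expressed throughout endoderm, had signals of 1488 and 1023, less than 2-fold apart.

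Genes of several signalling pathways differed. Markers of other cell types differed as well, and how much of the pathway differences came from such cells was not tested. Of 13 measured Notch genes 9 were higher and 1, DLL1, was lower, though within 2-fold at −0.90 in log2 with scaling on hybridisation controls. The list had a median of 1.18 above all random lists, and 0.68 over the median of probe sets. The target gene HEY1 was 14.3-fold higher, the receptor NOTCH1 5.65-fold, and NOTCH2 5.28-fold, with 1 of 4 other probe sets of NOTCH2 going the other way. Of 25 FGF genes 10 were higher and 4 lower, with a median of 0.61, or 0.31 without scaling. FGF19 was 7.93-fold and FGF3 5.11-fold higher, whereas FGF13 was 4.72-fold lower. Retinoic acid genes split, 4 of 15 higher and 5 lower. The retinoic acid degrading enzyme CYP26C1 was 13.6-fold higher, and RDH10, which makes retinal, was 9.33-fold lower. Wnt genes, with 7 of 36 higher and 8 lower, and BMP, Nodal and TGF-beta genes, with 10 of 38 higher and 8 lower, had medians of −0.01 and −0.02. FZD4 was 8.78-fold higher, ID1 8.24-fold higher and BMP5 at least 9.94-fold lower. Of 8 Hedgehog genes, PTCH1 was 3.43-fold and GLI2 3.41-fold higher and none was lower. Taken as the median over all probe sets of the gene, where probe sets at the floor count as no difference, NOTCH1 at 0, NOTCH2 at 0.70, GLI2 at 0.89 and BMP5 at −0.94 in log2 were within 2-fold.

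Markers of other cell types also differed. The endothelium list had 13 of 15 measured genes higher, none lower and a median of 3.81, above all random lists, with FLT4 28.1-fold higher and TEK at least 27.4-fold, or 3.19 in log2 over the median of its probe sets. The 2 other measured probe sets of FLT4 had a median log2 difference of 0.75, and the median over all its probe sets was 0.36, within 2-fold. The blood list had 7 of 8 measured genes higher and a median of 1.70, or 0.91 over the median of probe sets, led by CA2 at 40.1-fold and LMO2, shared with endothelium, at 18.7-fold. The lateral and gut mesenchyme list had 12 of 18 genes higher and 1 lower and a median of 1.38, above all random lists, and 0.86 with a floor at the 60th percentile. POSTN was at least 16.2-fold and LUM, a matrix proteoglycan, at least 12.8-fold higher, while PDGFRA was at least 8.93-fold lower. Cardiac mesoderm genes had 3 of 16 higher, 3 lower and a median of −0.07, and paraxial mesoderm genes 2 of 11 higher, 5 lower and a median of −0.04. Over the alternatives these medians ranged from −0.69 to 0.62 and from −1.28 to 0.36. The paraxial gene MSGN1 was at least 37.5-fold lower. The basement membrane list had 11 of 26 genes higher and 1 lower with a median of 0.95, which became 0.27 over the median of probe sets, among them perlecan, HSPG2, at 6.74-fold and COL4A2 at 4.72-fold. The immediate early list, whose genes also respond to handling of tissue, had 10 of 17 genes higher, 1 lower and a median of 1.07. EGR1 was at least 16.0-fold higher. Foregut and mid/hindgut endoderm were both freed from mesenchyme with collagenase, and early endoderm was not.

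The remaining genes at the extremes of this comparison were EMP1, 67.2-fold higher by its brighter probe set and 3.99 in log2 over the median of both, ANGPT2, an angiopoietin that binds the endothelial receptor TEK, 52.7-fold higher, WFDC1, at least 37.2-fold higher, and the matrix metalloproteinase MMP2, at least 35.2-fold higher. RBP4A, a retinol-binding protein gene, was 61.6-fold lower at 43.0 against 2649, ASTL at least 47.8-fold lower, GHRH 27.4-fold lower and CCDC3 26.4-fold lower, with a log2 difference of −2.38 for CCDC3 over the median of its probe sets. Of 10822 measured genes, 1146 were at least 2-fold higher in foregut and 703 lower, and 275 and 171 passed 4-fold. Technical spread alone, simulated 100 times, gave a mean of 106 genes higher and 103 lower. Without any scaling the split was 742 higher and 1213 lower, and with scaling on hybridisation controls it was 2467 and 381. In 528 genes the brighter of 2 probe sets above the floor on all arrays differed by 2-fold. In these genes the second probe set had the same sign in 92.6% and was itself 2-fold different in 51.9%. Over the median of all probe sets of a gene, 64.7% of the higher and 74.7% of the lower genes kept their call.

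The second comparison set mid/hindgut endoderm against early endoderm and asks the same of the back of the gut. Most measured HOX genes, which mark position along the body axis, were higher in mid/hindgut. HOXA7 had a signal of 2841 against values below the floor in early endoderm, at least 128-fold higher, with a log2 difference of 3.83 over the median of its probe sets. GUCA2B, the intestinal peptide uroguanylin, was at 9887 against 23.4, 422-fold higher. Most measured genes of the gastrulation list were lower, among them OTX2, a head and anterior endoderm factor, at 29.8 against 2101, 70.4-fold, and CER1, at least 119-fold. Endothelial and haemoglobin genes were higher, with CDH5 at 4330.5 and at least 196-fold above early endoderm.

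Of the HOX genes of paralog groups 1 to 4, 5 of 8 measured were higher and none lower, with a median log2 difference of 2.05, and 0.96 over the genes above the floor on all arrays. HOXA4 was at least 43.5-fold and HOXD4 at least 38.1-fold higher, HOXA3 14.6-fold, and HOXB4 at least 4.90-fold, while HOXB1 had signals of 444 and 462 and HOXB2 of 40.9 and 44.8. Of groups 5 to 8, 8 of 9 were higher, with a median of 3.01 above all random lists, or 1.63 over the median of probe sets, and HOXC8 lay just above the floor at 22.7. HOXA6 was at least 48.7-fold, HOXB7 20.3-fold, HOXB5 9.49-fold, HOXB6 at least 8.04-fold, HOXD8 at least 8.03-fold, HOXA5 at least 4.95-fold and HOXB8 at least 3.07-fold higher. Over the median of its probe sets HOXB6 had a log2 difference of 0, since its other probe sets lay at the floor, and HOXB7 had 2.17. With a floor at the 60th percentile HOXB4 at 0.84, HOXA5 at 0.86, HOXB8 at 0.17 and HOXA13 at 0 in log2 were within 2-fold. Of groups 9 to 13, 4 of 6 measured were higher, HOXA9 by 17.9-fold, HOXC9 by at least 9.92-fold, HOXD10 by at least 7.47-fold and HOXA13 by at least 2.36-fold. A second probe set for HOXD10 had a log2 difference of 0.25. The median of groups 9 to 13 was 2.07, or 0.69 without scaling, and of these genes HOXA10 alone was above the floor on all arrays. HOXA10 had signals of 58.8 and 48.5 and HOXA11 12.9 and 27.1. HOXB13, HOXC11, HOXD11, HOXD12 and HOXD13 were not above the floor on any array.

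**Figure D1:**
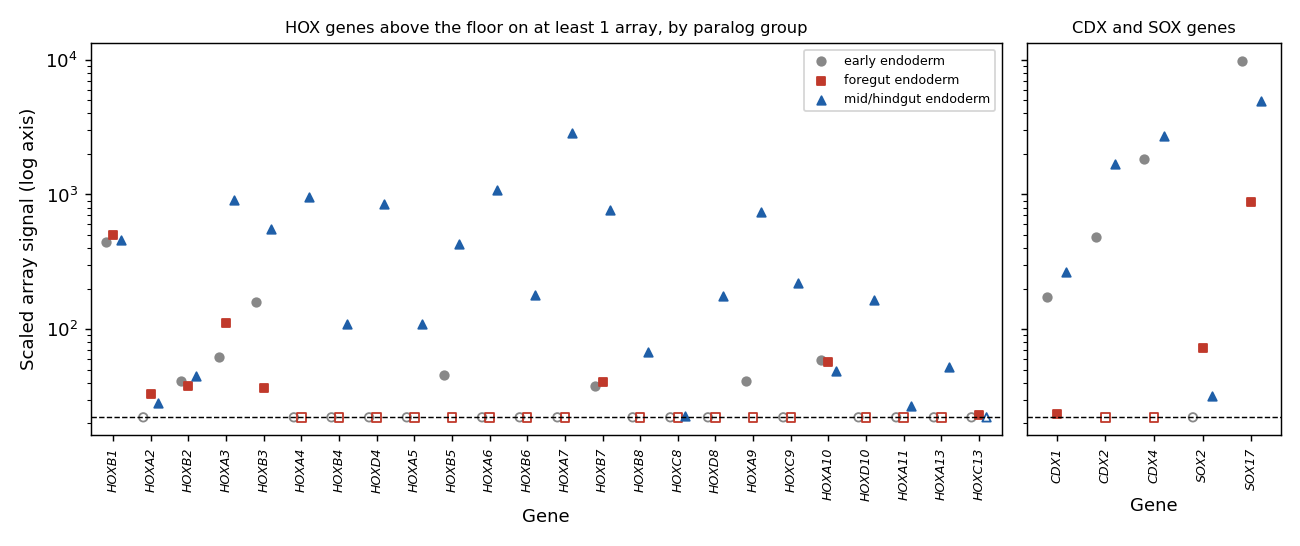
Scaled array signal on a log axis for HOX genes in order of paralog group and for CDX1, CDX2, CDX4, SOX2 and SOX17, with 1 point per array for early endoderm (circles), foregut (squares) and mid/hindgut (triangles). The dashed line is the floor of 22.1 and open symbols on it are values at or under it; HOXA7 reaches 2841 in mid/hindgut and lies below the floor on both other arrays.

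The mid/hindgut patterning list had 6 of 12 measured genes higher and 2, WNT11 and HNF4A, lower, with a median of 0.82 above 99.97% of random lists. Over the median of their probe sets WNT11 had a log2 difference of 0 and HNF4A of −0.69, within 2-fold. The posterior homeobox gene EVX1 was 5.93-fold higher, WNT5A 4.27-fold and MNX1 3.59-fold. CDX2 was 3.53-fold higher at 1694 against 479.7. CDX1 and CDX4 were already present in early endoderm at 173 and 1844 and were at 264 and 2739.5 in mid/hindgut, less than 2-fold apart. TBXT, at 2420.3 in mid/hindgut and 3598 in early endoderm, was also within 2-fold. Of the paraxial mesoderm list, 10 of 15 genes on the array were above the floor in early endoderm. Among them MSGN1 was at 830 there, below the floor in foregut and at 376 in mid/hindgut. Whether streak and posterior transcripts came from endoderm or from mesoderm in the pools was not tested. SHH was at 181 and below the floor in early endoderm, at least 8.19-fold higher. PTCH1, at 2.29-fold, was the other of the 8 Hedgehog genes that was higher, with 0.75 in log2 over the median of its probe sets.

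The gastrulation list had 16 of 22 measured genes lower and 1, WNT3A, 2.27-fold higher, or 0.92 in log2 without scaling, with a median of −2.65 below all random lists. The organiser gene GSC was at least 25.2-fold lower and the Nodal co-receptor gene CFC1 24.7-fold lower. The foregut patterning list had 6 of 15 genes lower and 2 higher, with EYA2 22.1-fold, IRX2 at least 6.88-fold and IRX1 at least 6.55-fold lower, and a median of −0.15. NKX2-1 was 2.38-fold lower, or −0.91 in log2 with a floor at the 60th percentile. SOX2 had a signal of 31.7 and was below the floor in early endoderm, at least 1.43-fold apart. SOX17 was at 4947 against 9773 and FOXA2 at 868 against 1488, both within 2-fold, though a second probe set for SOX17 had a log2 difference of −3.13. The endoderm factor list had 3 of 11 genes higher and 2 lower and a median of −0.29, with GATA6 2.71-fold lower.

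The list of liver, pancreas and intestine differentiation had 6 of 13 measured genes higher and 2 lower, with a median of 0.68, or 0.23 over the median of probe sets, and 10 more on the array lay above the floor in neither sample. The thyroid hormone carrier TTR was at 4718 against 87.5, 53.9-fold higher, and the fibrinogen chains FGB and FGG were 29.0-fold and 10.6-fold higher. Over the median of its probe sets TTR had a log2 difference of 2.88 in place of 5.75. Retinoic acid genes had 3 of 15 higher and 7 lower and a median of −0.93, at percentile 0.01 of random lists, though the median was 0.06 over the genes above the floor on all arrays. The retinoic acid making enzymes ALDH1A3 and ALDH1A2 were 12.2-fold and 6.22-fold lower, and CYP26C1 was 4.79-fold lower while CYP26B1 was 4.98-fold higher. Wnt genes had 8 of 36 higher and 9 lower with a median of −0.04, and SFRP1 was lower at 162 against 1136, with 1 of 2 other probe sets going the other way. BMP, Nodal and TGF-beta genes had 7 of 37 higher and 8 lower with a median of −0.18. MSX2 was higher at 554 against 79.2 and SMAD9 6.62-fold lower. Of 23 FGF genes 3 were higher and 3 lower with a median of 0.36, and of 12 Notch genes 4 were higher and none lower with a median of 0.55. Without scaling these medians were 0.10 and 0.29. FGF18 was 5.15-fold lower and NOTCH1 5.76-fold higher, and a second measured probe set for NOTCH1 had a log2 difference of 0.36, with 0 over the median of its probe sets.

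Markers of other cell types differed in this comparison too. All 8 measured blood genes were higher with a median of 4.03. The globin genes HBBR, at least 32.4-fold, HBZ, 24.8-fold, and HBA1, 23.0-fold, stood beside LMO2 at 28.0-fold. The endothelium list had 14 of 15 genes higher, none lower and a median of 3.95, or 2.02 over the median of probe sets, with TEK at least 32.5-fold and FLI1 29.9-fold higher. Lateral and gut mesenchyme genes went both ways, 4 of 16 higher and 4 lower, with a median of 0.18. POSTN was at least 9.93-fold higher and COL1A2 6.27-fold lower. Cardiac genes had 1 of 16 higher, 4 lower and a median of −0.01, and paraxial genes none of 11 higher, 4 lower and a median of −0.32. The basement membrane list had 9 of 27 genes higher and none lower with a median of 0.67, which became 0.15 over the median of probe sets, with the collagen IV genes COL4A2 and COL4A1 6.12-fold and 5.86-fold higher, though COL4A1 had a log2 difference of 0 over the median of its probe sets. The immediate early list had 9 of 19 genes higher, none lower and a median of 0.96, with EGR1 at least 14.9-fold and DUSP1 4.34-fold higher.

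**Figure D2:**
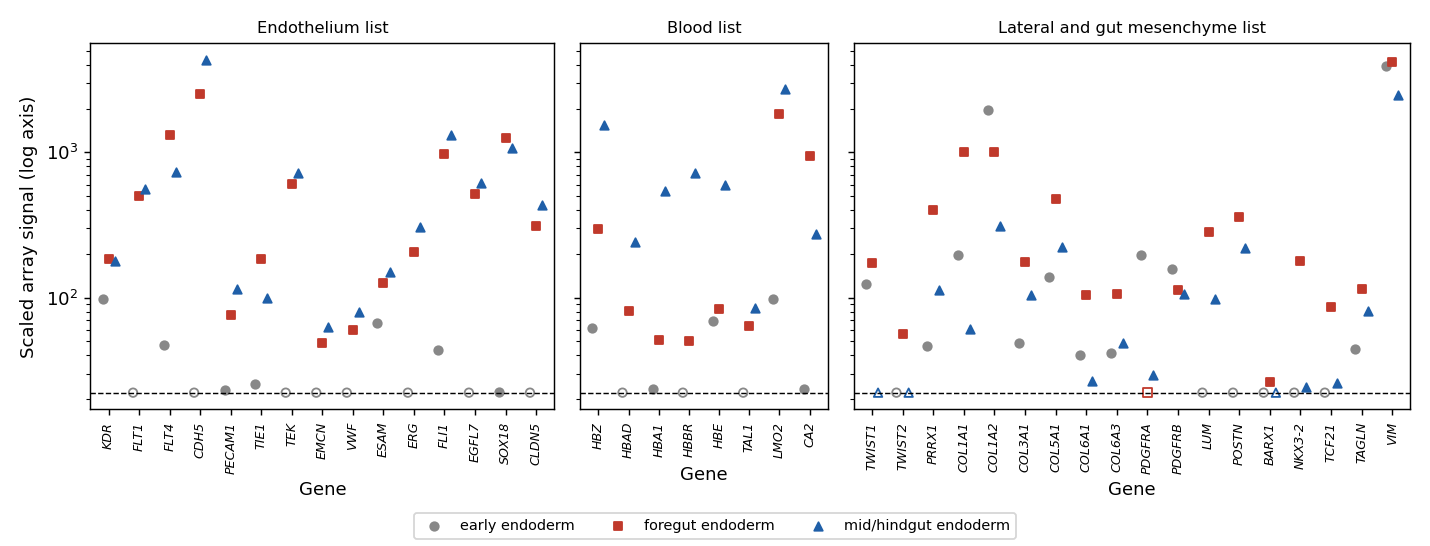
Scaled array signal on a log axis for genes of the endothelium, blood and lateral and gut mesenchyme lists above the floor on at least 1 array, with 1 point per array for early endoderm (circles), foregut (squares) and mid/hindgut (triangles). The dashed line is the floor of 22.1 and open symbols on it are values at or under it; CDH5 was at 2535 in foregut and 4330.5 in mid/hindgut, and HBBR at 50.2 and 718.

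Further genes at the extremes were FLRT1, at 9632 against 60.4 and 160-fold higher, GREB1, at least 124-fold higher, or 5.15 in log2 over the median of its probe sets, the homeobox gene NKX6-1, 63.3-fold higher at 2436, F2RL2, at least 51.0-fold higher, and SOX18, 47.6-fold higher. The annotation identifier behind FLRT1 was not found in the current gene table, so its older name is kept. CCDC3 was 87.1-fold lower, with a log2 difference of −2.38 over the median of its probe sets in place of −6.45, the pepsinogen gene PGA3 at least 34.0-fold, the hyaluronan synthase HAS2 33.6-fold, PKDCCA 28.5-fold and LMO1 at least 25.7-fold. Of 10766 measured genes, 874 were at least 2-fold higher in mid/hindgut and 553 lower, and 251 and 145 passed 4-fold. Technical spread alone gave means of 24.4 and 30.5. The split was 629 higher and 851 lower without scaling, and 715 and 684 when arrays were scaled on ribosomal protein genes. In 351 genes the brighter of 2 probe sets above the floor on all arrays differed by 2-fold. In these genes the second probe set had the same sign in 94.9% and was itself 2-fold different in 58.1%. Over the median of all probe sets of a gene, 69.2% of the higher and 70.9% of the lower genes kept their call.

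The third comparison set foregut directly against mid/hindgut endoderm and asks how front and back of the gut tube differ. The foregut pool was also older, at stages 10 to 11 against 8 to 10, so position cannot be told from stage in any difference below. Most measured genes of the foregut patterning list were higher in foregut, led by OTX2 at 3110.4 against 29.8, 104-fold, and NKX2-5, at least 73.6-fold. Most measured posterior patterning and HOX genes were lower in foregut, led by CDX4, at least 124-fold, HOXA7, at least 128-fold, and CDX2, at least 76.5-fold, for which 1 of 2 other probe sets went the other way. Over the median of probe sets HOXA7 had a log2 difference of −3.83 and CDX2 of −4.39. Most genes of the lateral and gut mesenchyme list were higher in foregut, 5 globin genes were higher in mid/hindgut, and none of the 15 measured genes of the endothelium list differed by 2-fold.

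The foregut patterning list had 12 of 19 measured genes higher in foregut and 2, DLX5 and SALL1, lower, with a median log2 difference of 1.30 above all random lists. DLX5, at −0.64 over the median of its probe sets, and SALL1, at −0.56 with scaling on hybridisation controls, were then within 2-fold. EYA2 was 28.2-fold and PAX9 15.9-fold higher, NKX2-1 3.01-fold at 144 against 47.7, and SOX2 2.28-fold at 72.2 against 31.7, or 0.26 in log2 with a floor at the 60th percentile. The mid/hindgut patterning list had 10 of 12 genes lower, none higher, and a median of −3.28. TBXT was 24.6-fold and CDX1 11.3-fold lower, and WNT3A was below the floor in foregut and at 442 in mid/hindgut. HOX genes of groups 1 to 4 had 5 of 8 lower with a median of −2.66, those of groups 5 to 8 had 8 of 9 lower with a median of −3.01, and those of groups 9 to 13 had 4 of 7 lower with a median of −1.24. None was higher by 2-fold, and with groups 5 to 8 taken over the median of probe sets their median was −1.82. HOXB3 was 15.2-fold lower in foregut and HOXA9 at least 33.4-fold, while HOXB1 was at 498 in foregut, HOXA2 at 33.1 and 28.3, and HOXC13 at 22.9 and below the floor. Over the median of their probe sets HOXB3 had a log2 difference of −2.48 and HOXA9 of −3.365. Of groups 9 to 13, HOXA10 alone was above the floor on all arrays.

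The endoderm transcription factor list had 4 of 12 measured genes lower in foregut and none higher, with a median of −0.68 at percentile 0.02 of random lists. SOX17 was 5.63-fold, GATA6 3.01-fold, GATA5 2.73-fold and ELF3 2.04-fold lower. With scaling on hybridisation controls the list median was −0.11, and GATA5 at −0.88 and ELF3 at −0.46 in log2 were within 2-fold. HHEX was at 1603 and 1308 and FOXA2 at 1023 and 868, within 2-fold. The gastrulation list had 7 of 19 genes higher and 3 lower with a median of 0.20, or 1.22 over the genes above the floor on all arrays, and GSC was at least 13.6-fold higher in foregut. Differentiation genes of liver, pancreas and intestine had 2 of 15 higher and 5 lower with a median of −0.43, which became 0.11 when arrays were scaled on hybridisation controls. TTR was 16.8-fold lower in foregut and the peptide hormone gene CCK 14.2-fold higher. A second probe set for CCK had a log2 difference of 1.05, with 2.44 over the median of both.

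Among signalling genes, CYP26C1 was 65.0-fold higher in foregut, or 4.43 in log2 over the median of its probe sets, and CYP26A1 6.95-fold lower, and the retinoic acid list had 3 of 15 genes higher and 2 lower with a median of 0.52, or 0.13 over the median of probe sets. Of 8 Hedgehog genes, SHH was 4.86-fold lower in foregut and CDON and SMO were 2.87-fold and 2.44-fold higher, and the median was 0.27. CDON had 0.94 over the median of its probe sets. FGF genes had 6 of 25 higher and 1, FGFR2, lower, though at −0.89 with scaling on hybridisation controls, with a median of 0.31, and FGF12 was 5.52-fold and FGF3 3.97-fold higher. Notch genes had 4 of 13 higher and 1 lower with a median of 0.39, and HEY1 was 10.4-fold higher. Wnt genes had 6 of 36 higher and 7 lower, and BMP, Nodal and TGF-beta genes 7 of 37 higher and 4 lower, with medians of 0.17 and 0.15. MSX2 was 16.9-fold lower and BMP7 higher at 1733 against 289. FZD8 was higher at 1178 against 47.2 by its brighter probe set, but its other probe set had a log2 difference of −0.22.

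The lateral and gut mesenchyme list had 11 of 18 measured genes higher in foregut and none lower, with a median of 1.23 above all random lists, and 0.80 with a floor at the 60th percentile. The collagen gene COL1A1 was 16.4-fold higher at 1000.2 against 61.0, TWIST1 at least 7.85-fold and NKX3-2, a gene of stomach mesenchyme, 7.38-fold. Over the median of its probe sets NKX3-2 had a log2 difference of 1.44. The blood list had 5 of 8 genes lower in foregut and 1, CA2, 3.45-fold higher, with a median of −1.97 that was nearer 0 with scaling on hybridisation controls, and HBBR was 14.3-fold and HBA1 10.6-fold lower. The 15 measured endothelial genes had a median of −0.25, which became 0.32 when arrays were scaled on hybridisation controls. Neural ectoderm genes had 8 of 17 higher and 4 lower with a median of 0.74, which became 0.06 without probe sets shared between transcripts, GBX2 being 8.89-fold higher and NKX6-1 8.67-fold lower. Cardiac genes had 4 of 17 higher, 3 lower and a median of 0.08, and paraxial genes 3 of 11 higher, 3 lower and a median of −0.15. The epithelial junction list had 4 of 27 genes lower in foregut and none higher, with a median of −0.24 that became 0.43 with scaling on hybridisation controls. The desmosome genes PKP2 and DSP were 6.91-fold and 3.37-fold lower.

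Further genes higher in foregut were PKDCCA, 93.7-fold, the fast muscle troponin gene TNNC2, at least 47.2-fold, the glypican gene GPC3, 34.8-fold, ANGPT2, 29.5-fold, and CAPN8, 26.5-fold. Further genes lower in foregut were FLRT1, at least 435-fold, GUCA2B, 385-fold, TSPAN8, at least 64.1-fold, RBP4A, 49.3-fold, HOXA6, at least 48.7-fold, HOXA4, at least 43.5-fold, and HOXD4, at least 38.1-fold. Of 10929 measured genes, 695 were at least 2-fold higher in foregut and 627 lower, and 138 and 147 passed 4-fold, against simulated means of 43.3 and 36.8 from technical spread. With scaling on hybridisation controls the split was 2290 higher and 252 lower. In 296 genes the brighter of 2 probe sets above the floor on all arrays differed by 2-fold. In these genes the second probe set had the same sign in 94.6% and was itself 2-fold different in 51.0%. Over the median of all probe sets of a gene, 62.3% of the higher and 73.05% of the lower genes kept their call.

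**Figure D3:**
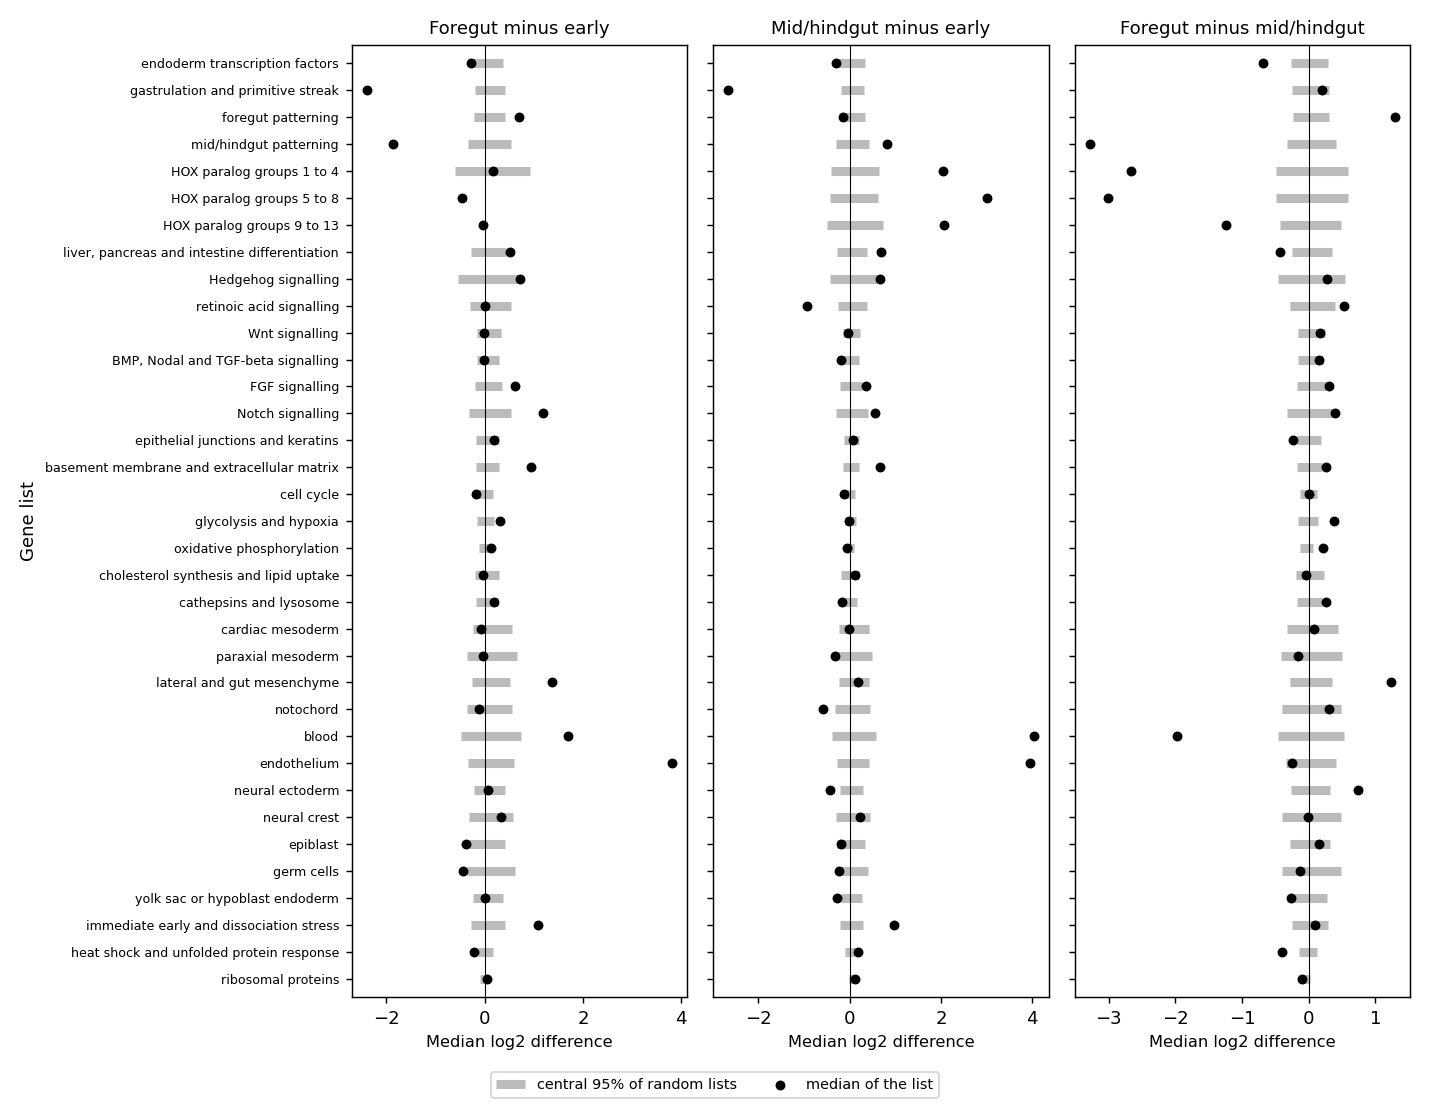
Median log2 difference of each of the 35 gene lists (points) in the 3 comparisons, beside the central 95% of 10000 random lists matched on mean level (grey bars, not drawn for lists with too few measured genes). The x axes are log2 differences of scaled signal with their own range per panel; the endothelium list lies at 3.81 and 3.95 against early endoderm and at −0.25 between the later samples.

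Of 63 ribosomal protein genes none differed by 2-fold, with medians of 0.05 for foregut against early, 0.13 for mid/hindgut against early and −0.10 for foregut against mid/hindgut, at percentiles 94.3, 99.98 and 8.78 of random lists. Of 33 cell cycle genes, CDKN1A, an inhibitor of cyclin-dependent kinases, was at least 6.57-fold higher in foregut and at least 5.07-fold higher in mid/hindgut than in early endoderm. CCNE2 was 2.65-fold and 2.08-fold lower and CCNE1 2.54-fold lower in foregut. Over the median of their probe sets CCNE2 at −0.99 and −0.85 and CCNE1 at −0.66 in log2 were within 2-fold. The cell cycle medians were −0.17, −0.12 and 0.01 in the same order of comparisons, at percentiles 1.14, 1.40 and 61.2. Of 47 oxidative phosphorylation genes, NDUFS3 was 2.89-fold lower in foregut than in early endoderm and 3.50-fold lower than in mid/hindgut, and the medians were 0.13, −0.06 and 0.22, at percentiles 99.4, 3.14 and 100. Cholesterol synthesis and lipid uptake genes had medians of −0.04, 0.11 and −0.04 and at most 1 gene past 2-fold in any direction. Of 26 glycolysis and hypoxia genes 6, 2 and 5 were higher and 1, 3 and 0 lower in the same order, with medians of 0.31, −0.01 and 0.38 at percentiles 99.92, 28.8 and 100, and the lactate dehydrogenase gene LDHA was 5.31-fold higher in foregut than in mid/hindgut. The glucose transporter gene SLC2A14 was 12.6-fold lower in foregut and 15.5-fold lower in mid/hindgut than in early endoderm.

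Taking the 3 arrays at once, 301 genes were at least 2-fold higher in early endoderm than in both later samples, 402 were highest in foregut and 292 in mid/hindgut. The genes lowest on 1 array numbered 462 in early endoderm, 240 in foregut and 168 in mid/hindgut. With scaling on hybridisation controls the numbers were 238, 1409 and 152 highest, and 512, 85 and 296 lowest, in the same order of samples. The 462 genes higher in both later samples than in early endoderm compare with 89.8 from independent lists and 6.37 from technical spread around a shared early array. The 301 genes lower in both compare with 34.8 and 9.50. The shared early array could not be split, so part of the excess may come from that array. Beside the genes above, the transcription factor genes MIXL1 and LHX1 were highest in early endoderm, at 390 and 308. MIXL1 rests on a probe set shared between transcripts, and its log2 difference was 0 in both comparisons without it. VEGFD and TLX1 were highest in foregut, at 390 and 364. The amino acid transporter gene SLC7A9 and APOH were highest in mid/hindgut, at 658 and 1748.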

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

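Of the tests in this part, those on the share of endoderm, on heart muscle, on the collagenase step and on heat shock were chosen after the results were seen. Those on further endothelial and further mesenchymal genes were written before their values were examined, except that the values of PALMD and MMP2, 1 gene in each list, had been seen.

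Probe sets for viral sequences were not part of the comparisons, and 5 of them exceeded 2 times the floor on at least 1 array. The brightest had signals of 1628 in early endoderm, 1635 in foregut and 1952 in mid/hindgut. A second had 96.62 in early endoderm, 45.86 in foregut and 96.19 in mid/hindgut.

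CDX2 went opposite ways in the later tissues, with a log2 difference from early endoderm of −4.437 in foregut and 1.82 in mid/hindgut. The foregut value is a bound, since the signal of 8.3 lay below the floor, and there 1 of 2 other probe sets went the other way and the median over probe sets was −2.59. In all, 18 genes were 2-fold higher in foregut and 2-fold lower in mid/hindgut than in early endoderm, among them PAX9, CYP26C1, GPC3 and COL1A1. Another 21 were lower in foregut and higher in mid/hindgut, among them WNT3A, MSX2, MNX1 and HOXB5. Some of these differences were small, with PAX9 2.03-fold and GPC3 2.39-fold lower in mid/hindgut. In foregut MSX2 was 2.41-fold and HOXB5 at least 2.05-fold lower. With a floor at the 60th percentile all of these fell within 2-fold. WNT3A in mid/hindgut was at 0.92 in log2 without scaling. The counts of 18 and 21 were not set against technical spread or other settings. With 1 array per tissue the difference between the foregut and mid/hindgut differences was not tested, and the later tissues differ in stage as well as position.

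Endothelial genes stood higher in both later tissues, and endothelial cells in the dissected tissue could account for it. Further endothelial genes had a median log2 difference of 0.9581 in foregut, under the bound of 1 set beforehand, and 1.744 in mid/hindgut (1.616 without PALMD), so this test cannot tell. Both medians lay at percentile 100 of random lists, which the bound did not take into account. In foregut 13 of 26 of these genes were higher and 2 lower, and in mid/hindgut 17 of 27 were higher and 1 lower. A lower share of endoderm, lifting all other cell types alike, was tested only on cardiac and paraxial mesoderm. The endothelial median lay at least 3.852 and at most 4.269 log2 units above theirs. The largest standard deviation among list members was 2.057. In early endoderm 12 of 20 cardiac and 10 of 15 paraxial genes on the array were already above the floor, against 7 of 16 endothelial genes. Transcripts already present there could hide a lift of those lists, so this test cannot decide on an equal lift. Blood and mesenchyme lists also stood higher, with medians of 1.70 and 1.38 in foregut and 4.03 and 0.18 in mid/hindgut. A lower share of endoderm, with an equal or an unequal lift, was therefore not excluded. Expression by endoderm itself was not separated from added cells.

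Mesenchymal genes stood higher in foregut than in mid/hindgut, and mesenchymal cells left on the foregut endoderm could account for it. Further mesenchymal genes met the prediction set beforehand, with a median log2 difference of 0.829 at percentile 100 of random lists, and 0.9336 without MMP2. The bound on this median was lower than that for the further endothelial genes, so the 2 outcomes cannot be ranked. Whether heart muscle cells were present cannot be told, since 8 muscle genes went both ways, with a median of 0.1455 that lay 1.084 under that of the mesenchyme list, less than their standard deviation of 1.364. MYL4 and MYH7 were lower in foregut, whereas ACTC1 and TNNT2, and outside the 8 genes TNNI1, NKX2-5 and TNNC2, were higher there, though MYH7, TNNT2 and TNNI1 were within 2-fold with a floor at the 60th percentile, where ACTC1 was not followed. Mesenchymal genes switched on within foregut endoderm, or the later stage of the foregut pool, would give the same values as mesenchymal cells.

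Immediate early genes stood higher in both later tissues, which are also the 2 that had the collagenase step. Their median log2 difference was 0.9622 in mid/hindgut and 1.075 in foregut, but the tissue without the step is also the youngest, so this test cannot tell the step from stage. It replaced a first version that asked for 50% of measured genes at 2-fold and found 47.37% in mid/hindgut and 58.82% in foregut. That version fell under its bound in 1 tissue, but the 95% interval of 24.45% to 71.14%, which takes genes as independent, spans the bound, so it cannot tell either. A general heat shock or unfolded protein response was predicted to raise the median of its list in both later tissues, and neither median reached the bound. The median was 0.1913 in mid/hindgut, above 99.8% of random lists, with CHAC1, HSPB1 and HSPH1 (0.66 over the median of its probe sets) of 30 genes higher. In foregut it was −0.2098, at percentile 0.32, which became 0.26 with scaling on hybridisation controls. The mid/hindgut median lay 0.3087 under the bound, less than the largest standard deviation among list members of 0.6332, which is a spread of single genes. Over the alternatives the median reached at most 0.26 in foregut and 0.24 in mid/hindgut. A rise of the whole list to the bound was thus not seen. For a smaller rise, or one of a few genes, this test cannot tell.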

How the results depend on the processing

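No test in this part gave a p-value, and 4 alternatives, scaling on hybridisation controls, no scaling, the viral floor and leaving out marker genes, were chosen only after the results were seen. No paired analysis was possible because each group had 1 array, and the results come from no test. Over all alternatives 107 counts stayed within 1.5 times of the reported one and 61 did not. List medians stayed within the technical spread of the reported one in 1082 cases and left it in 174. That spread is of the log2 ratio of 1 gene, which is wide for the median of a list. Medians near 0 could therefore change sign and still count as staying. Direction was followed for values of at least 1 log2 unit, where 2 list medians turned; list medians nearer 0 turned under several scalings. By the naming rule 302 genes were followed, with 548 values at least 2-fold apart. All 548 could be followed in every setting but 4. These were genes above the floor on all arrays, which kept 329 and by construction ended none, leaving out shared probe sets, which kept 515, and 3-fold and leaving out marker genes, where no gene was followed. None turned direction, and the floor at the 60th percentile ended 83 of these differences, the median over probe sets 58, scaling on hybridisation controls 32, no scaling 21, leaving out shared probe sets 13 of 515, ribosomal protein scaling 8, quantile scaling 5, no floor 3 and the floor at the 20th percentile 2. Another floor or scaling could hardly turn a difference of that size, so the lack of turns says little about robustness. The 2 reversals were the HOX groups 9 to 13 when only genes above the floor on all arrays were kept. The value was then that of HOXA10 alone, at −0.28 for mid/hindgut against early and 0.25 for foregut against mid/hindgut, so no gene of these groups turned. Signal near the floor limits the dim genes, which lose their order there.

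Counts below run higher then lower for foregut against early, mid/hindgut against early, and foregut against mid/hindgut, then highest and lowest in early, foregut and mid/hindgut. At 3-fold, by construction fewer, they were 484 and 287, 413 and 246, 253 and 236, then 133, 132 and 128 highest and 191, 69 and 72 lowest. Without a floor, which lets dim genes count, they were 1910 and 1246, 1609 and 1115, 1343 and 1219, then 484, 665 and 537 highest and 939, 559 and 527 lowest. A floor at the 20th percentile gave 1390 and 899 for mid/hindgut against early, 1133 and 1021 for foregut against mid/hindgut, 605 and 458 highest in foregut and mid/hindgut, and 771, 412 and 357 lowest. A floor at the 60th percentile gave 728 higher in foregut than early, 520 and 358, 416 and 402, then 250 and 192 highest in foregut and mid/hindgut, and 267, 154 and 98 lowest. Keeping genes above the floor on all arrays left 200, 256 and 171 highest.

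Scaling on hybridisation controls gave 2467 and 381 for foregut against early, 2290 and 252 for foregut against mid/hindgut, 1409 and 152 highest in foregut and mid/hindgut, and 85 and 296 lowest there, with median log2 shifts of 0.51 and 0.58 in the foregut comparisons. Without scaling there were 742 higher and 1213 lower in foregut than early, 851 lower in mid/hindgut than early, and 473 highest in early, with shifts of −0.24 against early endoderm. The median over probe sets gave 449 higher in foregut than mid/hindgut, and 302 and 97 lowest in early and mid/hindgut. For these 3 settings the cause was not tested. Quantile, median and ribosomal protein scaling, the viral floor, leaving out shared probe sets and leaving out marker genes moved no count by over 1.5 times.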

Other observations

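The lists in this part were fixed beforehand, no test in it was chosen only after the result was seen, and genes highest in 1 tissue were picked after their values were seen. Among genes highest in mid/hindgut, SPP1 had signals of 140.2 in early endoderm, 144 in foregut and 2948 in mid/hindgut, the glucose transporter gene SLC2A2 was at 274 and the endocrine factor gene RFX6 at 232, both below the floor in early endoderm and foregut. In foregut, differentiation genes of liver, pancreas and intestine had 4 of 11 measured members higher than in early endoderm and 1 lower. Their median was 0.51, and 0.39 to 1.69 over the alternatives. CCK was 7.20-fold and FGG 5.71-fold higher, and a second probe set for CCK had a log2 difference of 2.10. Early endoderm held the signals of the phosphatase gene DUSP5, at 3085 against 317 in foregut and 326.5 in mid/hindgut, and of the hormone precursor gene POMC, at 408 against 32.3 and a value below the floor.

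Lists of other tissues went several ways. Germ cell genes had 2 of 9 higher and 4 lower in foregut than in early endoderm with a median of −0.45, or −0.08 with a floor at the 60th percentile, and 1 of 10 lower in mid/hindgut with a median of −0.24, which became 0.23 over the genes above the floor on all arrays. PIWIL1 was 9.22-fold lower in foregut. Epiblast genes had 1 of 9 higher and 3 lower in foregut with a median of −0.38, which became 0.09 when arrays were scaled on hybridisation controls, and 2 of 8 lower in mid/hindgut with a median of −0.18. SOX3 was 3.61-fold higher in foregut. Notochord genes had medians of −0.12 in foregut and −0.57 in mid/hindgut, and CHRD was 6.27-fold lower in mid/hindgut. Neural crest genes had medians of 0.33, which became −0.56 over the genes above the floor on all arrays, and 0.23, and SNAI2 was 6.89-fold and 6.83-fold lower. Neural ectoderm genes had medians of 0.07 and −0.43, and ZIC2 was 5.23-fold and 11.0-fold lower, with log2 differences of −1.40 and −1.86 over the median of its probe sets. Yolk sac or hypoblast genes had 4 of 19 higher and 7 lower in foregut and a median of 0.00, and 3 of 20 higher and 6 lower in mid/hindgut with a median of −0.27, where APOH was 35.0-fold higher. Cathepsin and lysosome genes had medians of 0.20 and −0.16, and LGMN was 4.26-fold and 4.76-fold lower. Epithelial junction genes had medians of 0.20 and 0.07, and CLDN5, also a member of the endothelium list, was at least 14.1-fold and 19.7-fold higher. GRHL1 was 5.65-fold lower in foregut, and the desmosome gene PKP2 13.7-fold higher in mid/hindgut.

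Among 10527 chicken probe sets without a gene name, 97 were at least 4-fold higher and 61 lower in foregut than in early endoderm. The numbers were 88 and 51 for mid/hindgut against early endoderm and 46 and 37 for foregut against mid/hindgut.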
